A study of Mus musculus with 4 samples.

How the data were processed

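Gene expression was measured by RNA sequencing of poly(A)-selected liver RNA from female mice of a C57BL/6 x 129S4/SvJae background. Per the labels' protocols, 1 μg of RNA per library was reverse transcribed with random hexamers. Strand marking is not stated, so antisense and overlapping genes cannot be separated. There were 2 wild-type and 2 Utx knockout libraries, each a pool of RNA from 2 mice, per the series' design text. All mice had received acetaminophen, so the effect of the drug itself cannot be measured. A p-value here measures the spread between pools, and a pool averages the mice in it.

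The authors deposited 1 table of FPKM (fragments per kilobase of gene length, relative to a library total) for 54149 genes, with gene lengths, biotypes and coordinates per the file headers. Of these genes, 348 are unannotated transcript models. Reads had been aligned with HISAT2 version 2.0.5 to mm10 (GRCm38.p6), per the submitters' processing notes. The counting program and the annotation release are not given in the sources used here. Each library has its own column, matched to its sample by genotype and replicate number, and 0 sample columns were left out. Of the gene identifiers, 99.0% were found in GENCODE release M21 on GRCm38, and 97.1% of those had the same coordinates, so coordinates are given as the table lists them.

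The product of FPKM and gene length was a whole multiple of a single step in each library for 100.0% of values above 0, within 0.01 read, so whole reads were recovered. They summed to 16580979, 16669038, 17804730 and 16330451 for wild-type replicates 1 and 2 and knockout replicates 1 and 2. The totals implied by the authors' FPKM were 1.02, 0.943, 1.00 and 1.05 times these sums, so the deposited values had been scaled by something other than the listed reads. The deposited FPKM were already balanced by the median of ratios: scaling by it called the same 564 genes. Between replicate pools the chi-square statistic per gene was 48.9 in wild-type and 38.1 in knockout, so no library was a copy of its replicate.

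FPKM were tested as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend). Genes with a mean of at least 1 FPKM over the 4 libraries entered, 11900 in all, and p-values were two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. The fit had 2 residual degrees of freedom and 2.59 prior degrees of freedom. Fold changes are on this log2 scale and understate the change of low genes. Of 44 gene lists, 40 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the 40 lists. Of 1150 list genes, 3 symbols were not found in the table. Among the list genes, 42 belong to more than 1 list, so results of lists that share members are not independent.

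The tests, gene lists and rule for named genes were fixed before the data were examined. The rule took Kdm6a, the 12 largest rises and 12 largest falls among protein-coding genes with an established symbol, an adjusted p under 0.05 and groups that did not overlap. It also took up to 4 members with the smallest p of each list described, and Nnt, Xist, Cyp2e1, Gclc, Gclm, Cdkn1a and Mki67 whatever their p. A few genes that the rule takes are not reported here.

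The test was tried on 20 simulated data sets of 11900 genes, with negative binomial reads at the real means and totals and 200 changed genes. It recovered 72.55% of genes changed 2-fold and 98.45% of those changed 4-fold. Of its calls, 11.8% were of unchanged genes, above the nominal rate, and 98.5% of these false calls were of genes with under 50 reads on average. Restricted to 10610 genes with at least 50 reads, 4.70% of calls were false. A list of 25 genes shifted 1.5-fold was called in 20 of 20 data sets, and 0 of 780 tests of unchanged lists were called. The simulated genes varied independently, so this does not test the preset correlation. All simulated genes also had the same dispersion (0.012), while real genes may differ in theirs. The rates of recovery and of false calls, and where false calls lie, therefore hold for that setting and may not carry over.

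Alternatives were the pseudocount, the filter on low values, the scaling, the limma variant, limma voom on recovered reads, protein-coding genes alone, a replicate block, leaving out each library, the correlation used for lists, limma fry and a fold limit. A further 3 were chosen after seeing the data: removing trends on GC content and gene length, rescaling to the listed reads, and a minimum of 50 reads. GC content came from the longest GENCODE M21 transcript and was known for 98.1% of tested genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.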

Results

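Liver RNA was sequenced from adult female mice that lacked Utx in the liver and from age- and sex-matched wild-type mice. Utx, listed as Kdm6a, encodes a demethylase that removes methyl groups from lysine 27 of histone H3. All mice had been fasted for 16 h and then received an intraperitoneal dose of 300 mg/kg acetaminophen (APAP), a drug that injures hepatocytes at high dose. Each group held 2 libraries, and each library was made from a pool of RNA of 2 mice. The time between dosing and tissue collection is not given in the sources used here. The recovered reads came to 16580979 and 16669038 in the wild-type pools and to 17804730 and 16330451 in the knockout pools. Alb, the albumin gene, took between 5.40% and 6.93% of the reads in each pool. Reads of the mitochondrial ribosomal RNAs, which have short or no poly(A) tails, made up 0.244% and 0.251% of the wild-type libraries and 0.108% and 0.158% of the knockout libraries. The libraries were poly(A)-selected, and 11900 genes with a mean of at least 1 FPKM were tested.

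Kdm6a transcripts were lower in both knockout pools but were not lost. Kdm6a (ENSMUSG00000037369, GRCm38 chromosome X, 18162575 to 18279936, plus strand) was measured at 3.40 and 3.85 FPKM in the wild-type pools and at 2.20 and 2.12 FPKM in the knockout pools. These values rest on 482, 507, 328 and 305 reads. The log2 fold change was -0.63 (SE 0.13, 95% confidence interval -0.98 to -0.28), with a limma adjusted p of 0.0715, short of the threshold of 0.05. The adjusted p was 0.0441 when only protein-coding genes were tested and 0.0335 with limma voom on the recovered reads. A value per gene cannot show a deleted exon, and liver cells other than hepatocytes may keep the gene, so this measurement checks the labels only in its direction. Of the KDM6, MLL3/MLL4 and PRC2 list, which also holds Kmt2a and Kmt2b, 19 members were tested. Kdm6b, the paralogous demethylase, was the only member past the threshold: it fell from 19.3 ± 0.335 to 5.78 ± 0.968 FPKM (SD, n = 2 pools, limma adjusted p = 0.0258). Xist, expressed from the inactive X chromosome, was at 38.4 ± 2.74 FPKM in wild-type and 53.99 ± 0.934 in knockout pools (adjusted p = 0.0811), and the 6 Y-linked genes of a fixed list were listed at 0 in all 4 libraries.

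The comparison of knockout with wild-type livers asks which transcripts depend on hepatic Utx during acetaminophen exposure. Among the fixed gene lists, immediate early genes were lower in the knockout (median log2 fold change -2.21, camera adjusted p = 9.08e-15) and genes of bile acid synthesis and transport were higher (median 0.78, adjusted p = 7.06e-05). Neither list passed with an estimated correlation, where both had an adjusted p of 0.868. That correlation is estimated from 2 residual degrees of freedom, so this test has little power. Adjustment tied the 15 lists that passed with the preset correlation at 0.868. Their unadjusted camera p ran from 0.056 for p53 targets to 0.48 for heat shock, with 0.149 for immediate early genes. The list calls thus depend on the correlation assumed. Cxcl2, which attracts neutrophils, fell from 26.7 ± 7.24 to 0.723 ± 0.255 FPKM (SD, n = 2 pools per group here and below). Cdh1, which encodes the adhesion protein E-cadherin, fell from 19.9 ± 1.04 to 0.814 ± 0.340 FPKM. Cyp7a1, the rate-limiting enzyme of classic bile acid synthesis, rose from 2.50 ± 0.388 to 26.6 ± 12.9 FPKM. In total 564 genes differed at a limma adjusted p under 0.05, of which 190 were higher and 374 were lower in the knockout. When FPKM were rescaled to each library's own listed reads, a setting chosen after seeing the data, the split was 211 higher and 255 lower. Neutrophil markers, with a median log2 fold change of -1.31, and the share of mitochondrial ribosomal RNA reads were lower in the same knockout pools as each gene group described below.

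The largest falls are given among called protein-coding genes with an established symbol and groups that did not overlap. The 12 were Cxcl2, Cdh1, Jun, Egr1, Igfbp1, Trib1, Ier2, Btg2, Dnajb1, Csrnp1, Il22ra1 and Ifrd1. Spp1 had a log2 fold change of -2.80 but did not pass (limma adjusted p = 0.0858). The log2 fold change of Cxcl2 was -4.46 (SE 0.25, limma adjusted p = 0.0258) and that of Cdh1 was -3.98 (SE 0.21, adjusted p = 0.0258). Jun, a subunit of the transcription factor AP-1, fell from 649.7 ± 81.3 to 68.4 ± 27.7 FPKM. Igfbp1, which binds insulin-like growth factors and is induced by fasting, fell from 244 ± 142 to 27.03 ± 9.05 FPKM. Trib1, a pseudokinase, fell from 119.7 ± 23.03 to 16.4 ± 4.71 FPKM. Il22ra1, a subunit of the interleukin-22 receptor, fell from 5.60 ± 1.75 to 0.494 ± 0.328 FPKM. Csrnp1 and Ifrd1 had log2 fold changes of -2.65 and -2.60. Cxcl2 lies on chromosome 5 (90903871 to 90905938) and Cdh1 on chromosome 8 (106603351 to 106670246) of GRCm38.

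By the same rule, the 12 largest rises were of Ptgds, Cyp7a1, Cyp2a5, Ppp1r3b, Cyp7b1, Cbr3, Akr1c14, Chdh, Nol3, Adh4, Apol7a and Scgb2b3. Ptgds, a prostaglandin D synthase, rose from 0.913 ± 0.0731 to 22.6 ± 15.8 FPKM, with a log2 fold change of 3.84 (SE 0.51, limma adjusted p = 0.0390). Ppp1r3b, which directs a phosphatase to glycogen, rose from 3.78 ± 0.835 to 22.3 ± 1.81 FPKM. Cyp7b1, an oxysterol hydroxylase, rose from 3.77 ± 0.113 to 21.3 ± 3.43 FPKM. Chdh, which oxidizes choline, rose from 8.51 ± 0.407 to 39.7 ± 4.76 FPKM, and Adh4, an alcohol dehydrogenase, from 12.4 ± 4.37 to 51.9 ± 1.58 FPKM. Akr1c14, Nol3 and Apol7a had log2 fold changes of 2.28, 2.08 and 2.07. Cyp2a5 rose from 142 ± 48.98 to 905 ± 124 FPKM, but its near-identical paralog Cyp2a4 was at 669.7 ± 270.2 and 473 ± 4.23 FPKM, so the division of reads between them is uncertain. Summed over both paralogs, the mean was 1.70-fold higher in the knockout. Scgb2b3 averaged 7.5 reads per library and is uncertain at this depth.

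**Figure D1:**
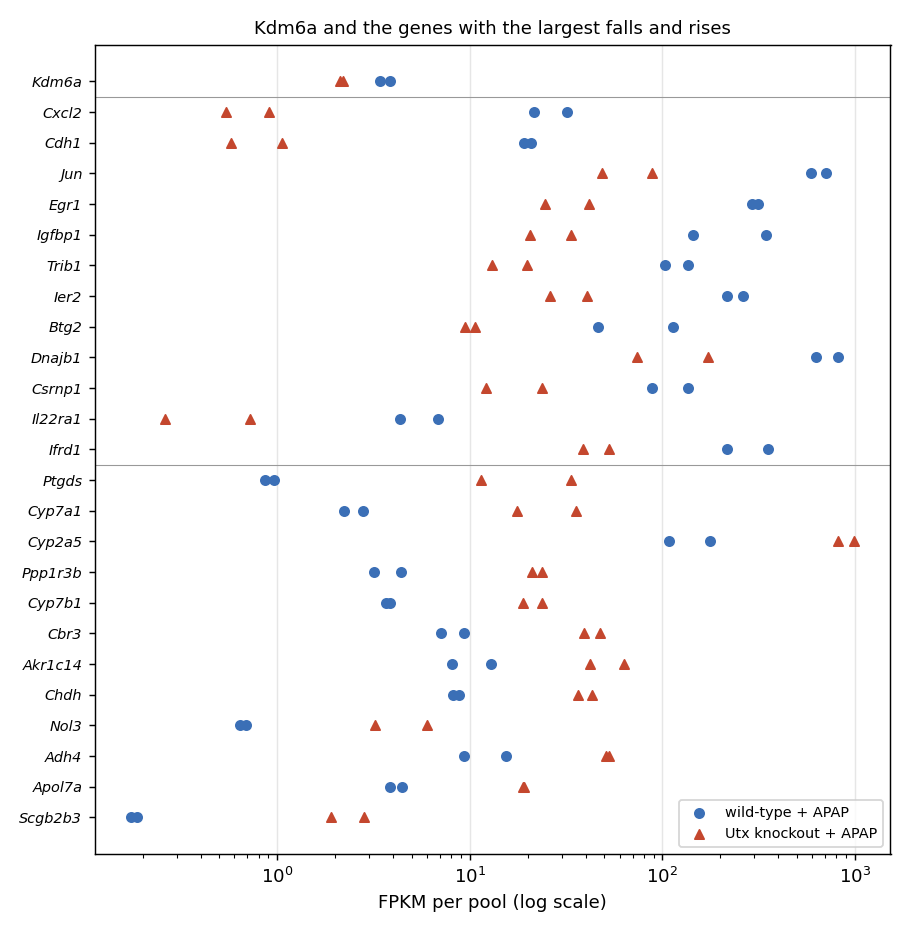
FPKM of Kdm6a and of the 12 largest falls and 12 largest rises, on a logarithmic axis. The falls and rises were picked among called protein-coding genes with an established symbol and groups that did not overlap. Each point is a pool of RNA from 2 mice, circles for wild-type and triangles for Utx knockout livers after APAP. The groups do not overlap for any gene shown, and Kdm6a in the knockout pools lies at 2.12 and 2.20 FPKM.

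Immediate early genes, which are transcribed within minutes of a stimulus, were lower as a group. Of 22 tested members, 15 fell, 0 rose and 7 did not pass, with a median log2 fold change of -2.21. Egr1 fell from 303 ± 16.2 to 33.01 ± 11.9 FPKM, Atf3 from 969 ± 64.5 to 167 ± 16.96, Junb from 95.1 ± 8.38 to 24.9 ± 2.07, and Klf6 from 129 ± 16.4 to 26.8 ± 4.12. Ier2 and Btg2 had log2 fold changes of -2.84 and -2.79. The camera adjusted p was 9.08e-15, and the adjusted p was 0.868 with an estimated correlation. Adjusted over the list alone, 19 members passed, all of them lower. In the same libraries the median of the neutrophil markers was -1.31.

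Targets of the unfolded protein response and of ATF4, a transcription factor of the integrated stress response, were also lower as a list. Atf3 is a member of both this list and the immediate early list. Of 29 tested members, 9 fell, 1 rose and 19 did not pass (median -0.53, camera adjusted p = 0.00894, adjusted p = 0.868 with an estimated correlation). With p-values adjusted over the list alone, 14 were lower and 4 higher. Ddit3, which encodes the pro-apoptotic factor CHOP, fell from 326 ± 30.4 to 53.8 ± 0.0743 FPKM, and Ppp1r15a from 72.9 ± 18.9 to 15.96 ± 0.881. Fgf21, a fasting hormone, fell from 34.6 ± 8.79 to 6.62 ± 1.56 FPKM. Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, was the member that rose, from 35.5 ± 5.66 to 79.6 ± 11.7 FPKM. Without wild-type replicate 2 the list did not pass, at a camera adjusted p of 0.0590.

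Of 26 tested p53 targets and cell death genes, 6 fell, 0 rose and 20 did not pass (median -0.32, camera adjusted p = 0.00134, adjusted p = 0.868 with an estimated correlation). When adjusted over the list alone, 11 were lower and 1 higher. Btg2, given above with the immediate early genes, is also a member of this list. Cdkn1a, the cell cycle inhibitor p21, fell from 201 ± 48.6 to 47.5 ± 17.6 FPKM, Trp53inp1 from 61.2 ± 21.96 to 10.5 ± 0.547, and Bbc3 from 10.99 ± 1.48 to 3.39 ± 0.364. Bcl2l1, which encodes an inhibitor of apoptosis, also fell, from 43.2 ± 6.33 to 15.7 ± 3.26 FPKM. The heat shock list was lower (median -0.71, camera adjusted p = 0.00361, adjusted p = 0.868 with an estimated correlation), but 1 of its 20 tested members passed on its own and 2 passed adjusted over the list alone. That member was the chaperone Dnajb1, at 724 ± 134 FPKM in wild-type and 124 ± 69.95 in knockout pools (limma adjusted p = 0.0498), and its call was lost in 11 of 19 alternatives. The heat shock call was lost without wild-type replicate 1 (camera adjusted p = 0.197) and without knockout replicate 1 (0.0916). Hspa1b, which shares nearly all its sequence with Hspa1a, was listed at 2000.3 and 546 FPKM in the wild-type pools and at 163 and 365 in the knockout pools, and did not pass.

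Inflammatory cytokines and chemokines were lower as a list, and so were neutrophil markers. Of 25 tested cytokine and chemokine genes, 5 fell, 0 rose and 20 did not pass (median -0.53, camera adjusted p = 0.000940, adjusted p = 0.868 with an estimated correlation). Adjusted over the list alone, 8 passed, all lower. Besides Cxcl2, Ccl9 fell from 12.3 ± 2.52 to 3.51 ± 0.150 FPKM, Nfkbiz from 25.4 ± 9.62 to 5.68 ± 0.503, and Il1rn, the interleukin-1 receptor antagonist, from 4.95 ± 0.381 to 2.43 ± 0.323. The call of Il1rn was lost in 10 of 18 alternatives. Of 15 neutrophil markers, 4 fell, 0 rose and 11 did not pass (median -1.31, camera adjusted p = 3.65e-05, adjusted p = 0.868 with an estimated correlation). Of these markers, 9 were lower adjusted over the list alone. S100a8 fell from 44.2 ± 11.1 to 11.01 ± 0.712 FPKM, S100a9 from 69.1 ± 19.1 to 16.97 ± 1.24, Clec4d from 3.93 ± 0.798 to 1.11 ± 0.0706, and Mmp9 from 2.69 ± 0.383 to 0.670 ± 0.0844. With a filter at a mean of 5 FPKM the neutrophil list did not pass (camera adjusted p = 0.0770).

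The other cell type lists had medians between -0.63 and 0.12. The Kupffer cell and macrophage list had a median log2 fold change of -0.13 (camera adjusted p = 0.211), with Cd163 the member of 25 that fell, from 13.2 ± 1.39 to 7.36 ± 0.433 FPKM. Without knockout replicate 2 the Kupffer cell and macrophage markers passed as lower (mean relative to other genes -0.42, camera adjusted p = 0.000481), and without knockout replicate 1 their mean turned to 0.11 (adjusted p = 0.488). Monocyte markers had a median of -0.10 (adjusted p = 0.211), with Ifitm6 the member of 10 that fell. The calls of Cd163 and Ifitm6 were lost in 10 of 19 and 10 of 17 alternatives. In these lists 2 Kupffer cell and 3 monocyte markers were lower, and 0 and 0 higher, adjusted over the list alone. The 5 tested lymphocyte markers had a median of 0.03 but a mean of -0.07 (adjusted p = 0.797), and hepatocyte identity genes had a median of 0.12 (adjusted p = 0.290), with 0 of 33 past the threshold. No lymphocyte or hepatocyte identity gene passed adjusted over the list alone. Hepatocyte identity passed as higher without wild-type replicate 2 (camera adjusted p = 0.0102) or knockout replicate 2 (0.0433). Sinusoidal endothelial markers were lower as a list (median -0.26, camera adjusted p = 0.00523, adjusted p = 0.868 with an estimated correlation), although the single member past the threshold, the fatty acid transporter Cd36, rose from 22.8 ± 0.592 to 64.4 ± 1.27 FPKM. In this list 2 were lower and 1 higher adjusted over the list alone. Stellate cell and fibroblast markers (median -0.16, camera adjusted p = 0.0432) and erythroid and platelet genes (median -0.38, adjusted p = 0.0432) passed as lists, each with an adjusted p of 0.868 with an estimated correlation. Col4a1, a basement membrane collagen, and Pf4, a platelet chemokine, were their members that fell, and the call of Pf4 was lost in 12 of 17 alternatives. Adjusted over the list alone, 4 of 27 and 1 of 7 passed, all lower. The endothelial, stellate and erythroid calls were each lost without at least 1 of the 4 libraries, at camera adjusted p of 0.121, 0.119 and 0.0857 without wild-type replicate 1. Of 9 cholangiocyte markers, Sox9 fell from 12.5 ± 2.01 to 3.13 ± 0.393 FPKM, 4 were lower adjusted over the list alone, and the list did not pass (median -0.63, camera adjusted p = 0.0694). The cholangiocyte markers passed as lower in 5 of 20 alternatives, among them without wild-type replicate 2 (camera adjusted p = 0.00706) and without knockout replicate 1 (0.0187), with adjusted p up to 0.868.

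Genes of bile acid synthesis and transport were higher as a list. Of 20 tested members, 7 rose, 1 fell and 12 did not pass (median 0.78, camera adjusted p = 7.06e-05, adjusted p = 0.868 with an estimated correlation). Adjusted over the list alone, 12 were higher and 2 lower. Akr1d1, a steroid reductase of bile acid synthesis, rose from 7.18 ± 0.698 to 23.3 ± 2.55 FPKM. The canalicular exporters Abcb11, for bile salts, and Abcg5, for sterols, rose from 16.2 ± 0.395 to 34.5 ± 0.628 and from 22.7 ± 0.0319 to 49.8 ± 0.684 FPKM. Cyp8b1, which directs synthesis toward cholic acid, was the member that fell, from 73.4 ± 0.944 to 38.96 ± 0.647 FPKM.

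Lipid synthesis lists were also higher. Of 24 cholesterol synthesis genes, 2 rose, 0 fell and 22 did not pass (median 0.57, camera adjusted p = 0.000180, adjusted p = 0.868 with an estimated correlation). Fdps, a farnesyl diphosphate synthase, rose from 1.45 ± 0.0229 to 3.72 ± 0.243 FPKM, and 2 members passed adjusted over the list alone. Of 21 fatty acid synthesis genes, only Acacb, an acetyl-CoA carboxylase that limits fatty acid entry into mitochondria, passed the limma test. It rose from 5.63 ± 0.913 to 15.2 ± 0.236 FPKM. The list had a median of 0.59 (camera adjusted p = 0.00134, adjusted p = 0.868 with an estimated correlation), and 6 members were higher and 1 lower adjusted over the list alone.

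Pericentral hepatocyte genes, which mark the zone around the central vein where acetaminophen is oxidized, were higher as a list. Of 32 members, 8 rose, 0 fell and 24 did not pass (median 0.40, camera adjusted p = 0.000893, adjusted p = 0.868 with an estimated correlation). The test adjusted over the list alone gave 12 higher and 2 lower. Among the 8 were Cyp7a1 and Cyp2a5, the latter uncertain against Cyp2a4. The nuclear receptor Nr1i2 rose from 11.6 ± 1.51 to 27.6 ± 0.554 FPKM and the transcription factor Tbx3 from 2.39 ± 0.244 to 5.90 ± 0.680. Periportal genes did not pass as a list (median 0.19, camera adjusted p = 0.170): 3 of 31 rose, among them Igfals and Cyp2f2, and Cdh1 fell. Adjusted over the list alone, 3 were higher and 1 lower, and the list passed as higher without wild-type replicate 2 (camera adjusted p = 0.0448) or knockout replicate 2 (0.0184).

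Of the genes that handle acetaminophen itself, the conjugation and glutathione transfer list was higher, with 1 of 29 members past the threshold (median 0.54, camera adjusted p = 0.0131, adjusted p = 0.868 with an estimated correlation). That member was Gsta3, a glutathione transferase, which rose from 90.9 ± 2.94 to 148 ± 1.08 FPKM, a call lost in 10 of 19 alternatives. Adjusted over the list alone, 8 members were higher and 1 lower, and the call was lost without wild-type replicate 1 (camera adjusted p = 0.258) or knockout replicate 1 (0.0601). The bioactivation list did not pass (median 0.17, camera adjusted p = 0.453). Adjusted over the list alone, 1 of 10 members was higher, Cyp2a5, whose division of reads with Cyp2a4 is uncertain. The list's mean relative to other genes was 0.35, and 0.53 without wild-type replicate 2. Cyp2e1, the main enzyme that oxidizes acetaminophen to its reactive product, was at 1367 ± 299 FPKM in wild-type and 1497 ± 12.9 in knockout pools (log2 fold change 0.15, 95% confidence interval -0.43 to 0.73, limma adjusted p = 0.699), and its log2 fold change was -0.077 without wild-type replicate 1. Gclc and Gclm, the subunits of the rate-limiting enzyme of glutathione synthesis, had log2 fold changes of -0.50 (adjusted p = 0.237) and 0.22 (adjusted p = 0.337). The NRF2 list did not pass (median 0.18, camera adjusted p = 0.170). Within it the carbonyl reductase Cbr3 rose from 8.18 ± 1.58 to 43.3 ± 5.62 FPKM and the cystine transporter Slc7a11 from 2.12 ± 0.788 to 7.52 ± 0.0185, while Osgin1 fell from 753 ± 175 to 199 ± 15.7. Over the NRF2 list alone the adjusted test gave 4 higher and 1 lower of 36, and the list passed as higher in 2 of 21 alternatives, with no filter (camera adjusted p = 0.0280) and without wild-type replicate 2 (0.0367).

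Nuclear-encoded subunits of oxidative phosphorylation were slightly higher as a list, with 41 of 42 members positive and 0 past the threshold (median 0.30, camera adjusted p = 3.08e-05, adjusted p = 0.868 with an estimated correlation), and 0 passed adjusted over the list alone. Mitochondrially encoded genes had a median of 0.13 (camera adjusted p = 0.401) and cytosolic ribosomal proteins a median of -0.01 (adjusted p = 0.797). Neither list had a member past the threshold, adjusted over all genes or over the list alone. Of 35 tested acute phase proteins, 25 had positive and 10 negative log2 fold changes, and the list did not pass (median 0.53, camera adjusted p = 0.0757). Among them Socs3, Hamp2 and Lcn2 fell, and Crp rose from 23.9 ± 2.20 to 63.6 ± 12.2 FPKM; adjusted over the list alone, 8 were higher and 6 lower. The list passed as higher in 3 of 21 alternatives, with camera adjusted p of 0.00419 without knockout replicate 2 and 0.0209 without wild-type replicate 2. Saa1, which shares sequence with Saa2, was at 57.96 and 303 FPKM in the knockout pools against 8.71 and 8.62 in the wild-type pools, and did not pass (limma adjusted p = 0.0679). Mki67, a proliferation marker, and Nnt, which carries a deletion in C57BL/6J mice, averaged 0.111 and 0.125 FPKM and were not tested.

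**Figure D2:**
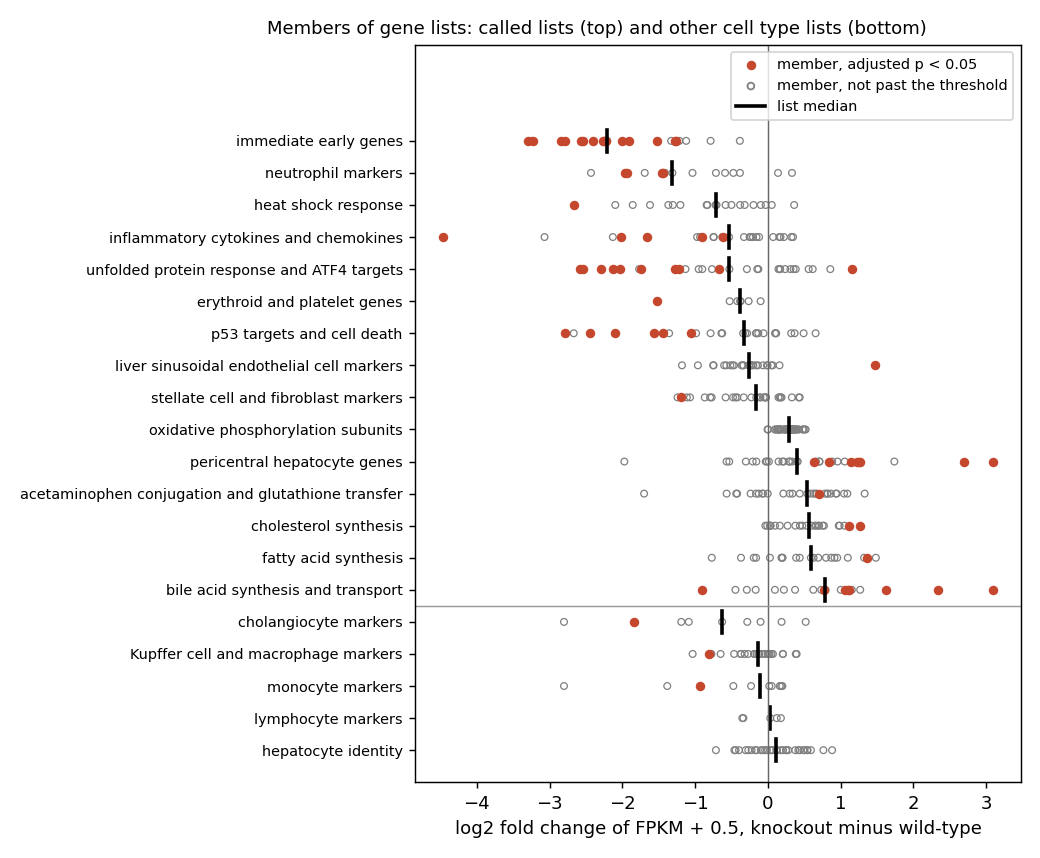
Log2 fold changes of FPKM + 0.5, knockout minus wild-type, of the tested members of 20 gene lists. The upper 15 lists passed camera with a preset correlation, and the lower 5 are other cell type lists. Filled points are members past the limma threshold, open points are the others, and black bars are list medians, from -2.21 for immediate early genes to 0.78 for bile acid genes.

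In all, 15 of 40 tested lists passed camera with a preset correlation of 0.01, 9 lower and 6 higher. With the correlation estimated, from 2 residual degrees of freedom and so with little power, 0 passed. The smallest adjusted p was then 0.868. The limma count rests on both pools of each group: it was 30 without wild-type replicate 1, 0 without wild-type replicate 2 (2662 genes at an unadjusted p under 0.05), 5 without knockout replicate 1 and 234 without knockout replicate 2. With no filter on low values limma called 0 of 26643 genes (4388 at an unadjusted p under 0.05). Of the 564 calls, 51 were of genes with under 50 reads on average. Most false calls fell there in the simulated data, in which all genes had the same dispersion.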

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

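Of the settings here, removing GC and length trends, rescaling to the listed reads and the minimum of 50 reads were chosen after seeing the data. Across 19 alternatives for single genes, 0 of the 24 genes with the largest changes turned direction. They had been picked for groups that did not overlap, so leaving out a library could not turn them. Their kept direction therefore adds no support. Of their 452 alternative values, 340 stayed past the threshold that they had been picked for passing. Depth limits the short genes: 1290 tested genes had under 50 reads on average.

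The count of 564 changed genes (190 higher, 374 lower) was 0 with no filter on low values (0 higher, 0 lower; limma, 4388 genes at an unadjusted p under 0.05), where 26643 genes share the adjustment. It was 280 (80 and 200) with no variance trend, 1105 (418 and 687) with voom on recovered reads, and 1014 (408 and 606) among protein-coding genes alone. It was 867 (322 and 545) with at least 50 reads, and a log2 fold limit of 1 left 384 (107 and 277). Leaving out 1 library gave 0 to 234 changed genes, 0 to 51 higher and 0 to 183 lower; all 564 kept their sign in each of these 4 fits, in which the lone pool is assumed to vary like the other group. The log2 fold change of Kdm6a passed in 2 settings, at -0.74 with voom and -0.63 among protein-coding genes alone, and its adjusted p ranged from 0.0335 to 0.216. The cause was not tested, except that fewer or more genes tested and fewer samples follow from the settings themselves. The 564 genes had been picked as called, which requires a change large against the spread between pools. Leaving out 1 library therefore could not turn their sign, and the kept signs add no support.

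With the replicate number as a block, 310 genes passed (74 higher, 236 lower), 266 of them among the 564, and Kdm6a stayed at -0.63. The labels give the numbers no shared meaning, and across genes the deviations of same-numbered pools correlated at -0.14, so the numbers were not read as pairs. The count of 15 lists was 18 under the block.

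The count of lists was 0 with camera's correlation estimated from 2 residual degrees of freedom and 0 with limma fry, which tests each list on its own (8 at an unadjusted p under 0.05). When members may move either way, fry passed 31 lists at an adjusted p under 0.05. With camera, leaving out 1 library gave 10 to 23 lists, 23 without wild-type replicate 2. Of the 25 lists that did not pass, 13 passed in at least 1 alternative, and all 13 of them did so without 1 of the libraries.

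Direction turned for 12 lists and 1 gene, none past its threshold in the values reported. Leaving out each library in turn, the log2 fold change of Cyp2e1 ran from -0.077 to 0.37. The mean log2 fold change relative to other genes ran from -0.37 to 0.15 for MHC class II and antigen presentation, from -0.094 to 0.020 for lymphocyte markers, from -0.42 to 0.11 for Kupffer cell and macrophage markers, and from -0.0076 to 0.30 for hepatocyte identity. It ran from -0.033 to 0.23 for periportal hepatocyte genes, from -0.31 to 0.015 for fatty acid oxidation and PPARA targets, and from -0.054 to 0.37 for mitochondrially encoded genes. It ran from -0.033 to 0.061 for cytosolic ribosomal proteins, from -0.24 to 0.023 for female-biased liver genes and from -0.023 to 0.073 for autophagy and lysosome. With a filter at 5 FPKM it was -0.018 for circadian clock, 0.017 for female-biased liver genes and -0.0031 for autophagy and lysosome, and with no filter 0.026 for lymphocyte markers. Among protein-coding genes it was -0.0016 for cytosolic ribosomal proteins and -0.043 for X-linked genes that escape inactivation and Xist. Cytosolic ribosomal proteins were at -0.028 with GC and length trends removed. With fry the plain means were -0.018 for cytosolic ribosomal proteins and -0.0074 for autophagy and lysosome. These are also the plain means at the settings used in the report, so only the measure differs and nothing turned there. The cause of the other turns was not tested.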

Other observations

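All tests of explanations in this part were chosen after the results were seen. Some genes of fasting, lipid use and hypoxia changed, but their lists did not pass as a whole and held members of both signs. Plin2, which coats lipid droplets, fell from 1040.2 ± 69.2 to 322 ± 66.9 FPKM (SD, n = 2 pools), Acot2 from 219 ± 30.5 to 59.8 ± 21.1, and Angptl4 from 129.96 ± 8.73 to 76.02 ± 1.74 (a call lost in 10 of 19 alternatives), while the fatty acid oxidation list had a median log2 fold change of 0.09 and a mean of -0.18 (camera adjusted p = 0.797). Of its 38 members 4 fell, 0 rose and 34 did not pass; adjusted over the list alone, 6 were lower and 1 higher. Irs2, an insulin receptor substrate, fell from 13.5 ± 2.25 to 5.80 ± 0.198 FPKM and Got1 from 111 ± 15.1 to 56.01 ± 3.44 (list median 0.06, mean -0.24, adjusted p = 0.531). Of 17 gluconeogenesis and fasting genes, 3 fell, 0 rose and 14 did not pass, 9 had positive and 8 negative log2 fold changes, and 3 were lower and 2 higher adjusted over the list alone. The glucose transporter Slc2a1 fell from 25.1 ± 2.02 to 7.30 ± 0.293 FPKM, Ndrg1 from 26.8 ± 6.90 to 4.37 ± 1.03 and Hif1a from 18.02 ± 1.39 to 9.58 ± 0.305, while the glycolytic enzyme Tpi1 rose from 121 ± 9.28 to 224 ± 17.6 (list median -0.07, adjusted p = 0.578). Of 21 hypoxia and glycolysis genes, 3 fell, 1 rose and 17 did not pass, with 6 lower and 2 higher adjusted over the list alone. The coagulation and complement list had a median of 0.18 (camera adjusted p = 0.0600), with 5 of 34 members higher and 2 lower adjusted over the list alone. It passed as higher in 5 of 21 alternatives, among them with no filter (0.0210), with quantile normalization (0.0477), and without wild-type replicate 2 (0.00123) or knockout replicate 2 (0.00419). Over all alternatives its mean relative to other genes ran from 0.083 to 0.32 and its adjusted p reached 0.868.

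Sex-biased genes changed in both lists, of which neither passed as a whole at the settings used in the report. Among 29 female-biased genes 4 fell, Cyp2b10, Sult1e1, Slc22a27 and Hamp2, and 0 rose (list median 0.05, mean -0.14, camera adjusted p = 0.620). Of these genes 16 had positive and 13 negative log2 fold changes, and 6 were higher and 9 lower adjusted over the list alone. Among male-biased genes 3 of 22 rose, Cyp7b1, Mup1 and Nudt7 (median 0.63, adjusted p = 0.0694), with 5 higher and 1 lower adjusted over the list alone. The male-biased liver genes passed as higher in 4 of 21 alternatives, among them with a filter at 5 FPKM (camera adjusted p = 0.0139) and without wild-type replicate 2 (0.00172) or knockout replicate 2 (0.00294). Over all alternatives the list's adjusted p reached 0.868. Mup1 belongs to a family of near-identical genes and is uncertain. The interferon-stimulated list had a median of 0.15 (adjusted p = 0.131), the MHC class II list -0.08 (0.591), the S phase list 0.30 (0.275), the autophagy and lysosome list 0.13 (0.797), the fetal and imprinted list -1.02 (0.131), the KDM6, MLL3/MLL4 and PRC2 list -0.09 (0.289) and the X-linked escape list 0.04 (0.797). In the first 3 of these lists no member passed adjusted over the list alone. In the others, likewise adjusted, 1 autophagy gene was higher and 2 lower, 2 fetal and 1 complex genes were lower, and 1 escape gene was higher and 1 lower. Leaving out knockout replicate 1, the interferon list and the S phase list passed as higher (camera adjusted p = 0.0180 and 0.00793), and leaving out wild-type replicate 2, the MHC class II list and the fetal list passed as lower (0.0304 and 0.0392). The interferon list also passed with no filter (0.0416). Rn7sk, a nuclear RNA that restrains transcription elongation and lacks a long poly(A) tail, fell from 115 ± 20.03 to 21.01 ± 1.19 FPKM. The mitochondrial mt-Rnr1 and mt-Rnr2 had log2 fold changes of -1.06 and -0.93 that did not pass (limma adjusted p = 0.0868 and 0.0854). Median log2 fold changes were -0.51 for 89 snoRNAs (74.2% negative), -0.52 for 40 snRNAs (70% negative) and -0.30 for 14 mitochondrial transfer RNAs. They were 0.53 for 5 scaRNAs and 0.02 for protein-coding genes (47.8% negative). Whether RNA or library preparation differed between the groups was not tested. Of 220 tested unannotated transcript models, 29 were lower and 6 higher, against 374 lower and 190 higher of all 11900 tested genes. Reads on all 348 such models made up 0.479% and 0.295% of the wild-type libraries and 0.178% and 0.196% of the knockout libraries. Within 10 Mb of Kdm6a, 3 of 42 tested genes were called (Mid1ip1, Maoa and Hypm, named after their values were seen), 7.14% against 4.74% of all tested genes (Fisher's exact p = 0.45).

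Immediate early genes were lower in both knockout pools. A trend on GC content or gene length is argued against, since with both trends removed the list's mean stayed 2.03 log2 units below that of other genes (value -2.03, SE over members 0.18). This SE leaves out the error between pools. Loss of neutrophil RNA is argued against as the whole cause, since the 22 members together lost 34.9 times the FPKM lost by S100a8 and S100a9. Handling of the mice or tissue cannot be told apart from genotype: pools of the same group differed by up to 0.630 in the list's mean against -2.03 between groups, but nothing in the labels shows that pools of both groups were handled together. Genotype stays open as an untested explanation, as does a different course of injury at collection.

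Neutrophil markers were lower, with a median log2 fold change of -1.31 against -0.13 for Kupffer cell and macrophage markers. A larger hepatocyte share of the RNA would lower all other cell types alike. Against it as the whole cause, the mean of 14 neutrophil markers lay below that of 25 Kupffer cell markers (value -1.01, SE over members 0.20). G0s2 was left out, since hepatocytes express it. Without wild-type replicate 2 the difference was -0.62 (SE 0.20). It was only -0.39 (SE 0.40) against cholangiocyte markers and -0.67 (SE 0.36) against monocyte markers, both within 2 SE. Spp1 belongs to both of these lists, with a log2 fold change of -2.80 that did not pass (limma adjusted p = 0.0858). It pulls both means down, so these differences are not independent. The median of the monocyte markers was -0.10. Each SE in this paragraph is over members, which vary together. The estimated correlation was 0.46 in the neutrophil list and 0.49 in the Kupffer cell list. Such an SE understates the error between pools. The values therefore lean against a larger hepatocyte share as the whole cause without settling it. As part of the cause it cannot be told apart from other explanations, since 107 markers of 7 other non-hepatocyte lists pooled were also lower, with a mean of -0.31 (SE 0.053), but their lists did not all fall beyond their error. The means were -0.80 for cholangiocytes (SE 0.35), -0.52 for monocytes (0.30), -0.51 for erythroid and platelet genes (0.18), -0.30 for stellate cells (0.097), -0.27 for endothelial cells (0.094), -0.18 for Kupffer cells (0.072; -0.46 without knockout replicate 2 and 0.089 without knockout replicate 1) and -0.07 for lymphocytes (0.11), against 0.11 for hepatocyte identity, a list that passed as higher without wild-type replicate 2 (camera adjusted p = 0.0102) or knockout replicate 2 (0.0433). Fewer neutrophils in the tissue may account for the rest, as may lower transcription of these genes per cell; neither was tested, and genotype stays open.

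Clock genes moved both ways. Of 20 tested members 3 rose, among them Usp2 and Hlf, and 2 fell, Nfil3 and Rora, with a list median of -0.12, a mean of 0.07 and a camera adjusted p of 0.797. There were 7 higher and 6 lower members adjusted over the list alone. Nr1d1 and Nr1d2 had log2 fold changes of -0.20 and -0.44 and did not pass (limma adjusted p = 0.518 and 0.269). Collection times are not given in the sources used here, and no explanation is weighed for this pattern.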
